A study of Homo sapiens with 4 samples.

How the data were processed

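RNA recovered with anti-FLAG beads from cytoplasmic lysates of HEK293 cells was hybridised to 4 Agilent human expression arrays with 2 colours each. Per the labels, Cy3 carried RNA from cells transfected with FLAG-tagged RNA helicase A (RHA, the product of DHX9) and Cy5 carried RNA from cells transfected with the empty FLAG plasmid, on all 4 arrays, without a dye swap. Dye and group are therefore confounded. The labels call the arrays biological replicates 1 to 4, from replicate plates. They do not say that each array had its own control immunoprecipitation, so the control was treated as 1 common control and the log2 ratio was tested against 0, which leaves out the control's own spread. All 4 arrays lay on a single slide, so no slide effect was fitted.

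The deposited scanner files hold, per the file headers, spot intensity values of both channels from Agilent Feature Extraction version 10.7.3.1, while the submitters' processing notes name version 10.9 and limma with no version given. Their median signal and median local background intensities were used as deposited, before any normalisation. The processed signals in the same files, used for an alternative, are background-subtracted and dye-normalised intensities per the file headers, and the deposited log10 ratio of Cy5 over Cy3 was used for the spike-in control probes. The authors' value table holds, from a comparison with the scanner values, log2 ratios of Cy5 over Cy3 close to a loess normalisation without background subtraction. Across the probes of an array its values had a Pearson r of 0.996, 0.993, 0.988 and 0.998 with such ratios on arrays 1 to 4, and their SD was 1.04, 1.06, 1.08 and 1.02 times as large. The medians of its columns were 0.01, -0.01, -0.01 and 0.01. Its scale, centring and direction come only from this comparison, and its exact normalisation is not given in the sources used here. Ratios below are log2 of Cy3 over Cy5, the opposite direction of the authors' table and of the scanner's log ratio.

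The plan fixed before the data were examined named mean signals and the files' gene names. The files used here hold median signals and accessions, so median signals were used, and genes were named by matching the accession of each probe, without its version, to the RefSeq table of assembly GRCh38.p14. Of 41000 distinct probes, 26222 received a symbol in this way, for 17721 genes, and 14778 kept their accession or probe name. JUND and COL1A1, planned as individual results, are not analysed here.

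Background was corrected with the normexp method and an offset of 50, and each array was loess-normalised with the 1639 control features at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform or as population outliers were left out on the array concerned, and 643 features carried such a mark on at least 1 array. No spot was saturated. Spots of 1 probe were averaged. A probe was kept if it was well above background, per the scanner's own mark, in the same channel on at least 3 of the 4 arrays, which left 25397 probes. Each gene took its kept probe with the highest mean intensity, for 19031 genes and unnamed transcripts, of which 12882 had a symbol. There were 4620 symbols with 2 or more kept probes. For the named genes among them the other probes were compared, and disagreements are given beside many of these genes.

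The ratio was tested with limma (lmFit with an intercept, then eBayes), 2-sided, with Benjamini-Hochberg adjustment at 0.05 over all 19031. Errors are the SD over the 4 arrays. The 22 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 where at least 3 members were measured, which held for 20 lists, with Benjamini-Hochberg adjustment over those 20. Camera with an estimated correlation and fry stand beside it. The rule for named genes, also fixed beforehand, took the 12 highest and 10 lowest mean ratios among genes with a named symbol, an adjusted p under 0.05, the same sign on all 4 arrays and a signal well above background on all 4 in the higher channel. It always took DHX9, JUND, JUN, COL1A1, COL1A2, GAPDH and ACTB where measured, and up to 4 members of each list with the smallest adjusted p, of which the first 2 are named; 2 genes that the rule took are not reported here. Since 0 genes met the adjusted p, the rule was applied without that criterion, and every named gene at least 2-fold toward 1 channel on each array was added. These changes were made after seeing the data.

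The pipeline was tested on 4 simulated arrays of 19031 genes with 200 changed genes. With an offset of 50 it called 1 of 67 genes changed by 1 log2 unit, 19 of 67 changed by 2 and 22 of 66 changed by 3, with 2 false calls, and the median estimate was 0.73, 0.737 and 0.714 times the true change. With an offset of 0 it called 2 of 67, 45 of 67 and 58 of 66, with 3 false calls, and the estimates were 1.02, 1.04 and 1.03 times the true change. Camera at the preset correlation found the simulated shifted list and called 0 of 20 null lists. Noise was drawn independently for each probe, so these lists had no correlation between genes. In the real lists the estimated correlation ran from -0.0509 to 0.665 and was 0.383 for the respiratory chain genes. The simulation thus cannot show whether the preset correlation limits false calls there. With an estimated correlation the simulated shifted list had an adjusted p of 0.273 at an offset of 50 and of 0.0446 at an offset of 0.

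The alternatives were the scanner's processed signals centred on the median without loess, no background subtraction, an offset of 0, median centring in place of loess, scaling between arrays after loess, no filter on dim probes, a filter for both channels on all arrays, marked spots kept, an intensity trend, array weights, the mean over a gene's probes, the authors' value table, each array left out in turn (with probes then kept if well above background on 2 of the 3 others), a test against a 2-fold change, and camera with an estimated correlation. Centring on the spike-in control probes, a rank product over 100 permutations and the 2 counts of genes 2-fold toward 1 channel on every array were added after seeing the data. The number of arrays limits the precision.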

Results

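The series asked which cytoplasmic mRNAs bind RNA helicase A (RHA, encoded by DHX9), a DEAH-box helicase reported to act on mRNAs with a structured 5' control element such as JUND. HEK293 cells, a human embryonic kidney line, were transfected with FLAG-tagged RHA or with the empty FLAG plasmid. After 48 h a cytoplasmic lysate of 200 µl was made from 150 mm plates, and RNA bound to anti-FLAG beads was eluted and labelled. There was 1 group of 4 arrays, each comparing the library labelled FLAG-RHA in Cy3 with the library labelled empty FLAG in Cy5. The Cy3 channel was dim. Its median signal above local background was 14.5, 12, 9 and 108 intensity units on arrays 1 to 4, against 40, 63, 205.5 and 566.5 in Cy5. The share of features well above background was 57.5, 57.2, 53.3 and 66.1% in Cy3 and 59.1, 62.8, 66.5 and 70.3% in Cy5.

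The first comparison assumed that DHX9, the gene of the tagged protein, would be higher in the library labelled FLAG-RHA. It was not. DHX9 was 5.54-fold higher in Cy5, the library labelled empty FLAG, with a log2 ratio of Cy3 over Cy5 of -2.47 ± 0.69 (SD, n = 4); this sign is opposite to that of the authors' value table, which runs Cy5 over Cy3. The values on arrays 1 to 4 were -2.86, -1.88, -1.90 and -3.24. Its other 2 probes gave -2.35 ± 0.92 and -3.01 ± 1.86 (SD, n = 4) and were below 0 on all 4 arrays. Whether the 3 probes lie within the transfected part of DHX9 was not determined here, so they may report only the cell's own transcript. Because the gene of the tagged protein went against that assumption, results are given by channel, and "the library labelled FLAG-RHA" or "empty FLAG" stands for the label alone. The adjusted p of DHX9 in limma was 0.307 over all genes. It was 0.00254 when adjusted over the list of RNA helicases alone. Over all genes it was 0.00161 with a background offset of 0 and 0.00296 with the scanner's processed signals. The number of calls in these last settings depended on array 4, as given below.

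The 10 lowest named genes, DHX9 among them, were taken only from those with the same sign on all 4 arrays. They were thus brighter in Cy5 on each array by that rule. C1QBP, a multifunctional protein of the mitochondrial matrix, had the lowest named mean, at -3.06 ± 1.88 (SD, n = 4), which is 8.33-fold higher in Cy5. It was followed by CIBAR1 at -2.88 ± 1.25 and by PPP3CB, a catalytic subunit of calcineurin, at -2.69 ± 0.94. HSPA8, the constitutive cytosolic HSP70 chaperone, was at -2.52 ± 1.20, and its 3 other probes had means between -2.54 and -1.93. COX18, a factor for cytochrome c oxidase assembly, was at -2.45 ± 0.87, with a second probe at -1.21. SRP19, a protein of the signal recognition particle, was at -2.38 ± 1.32, MRPL47, a mitochondrial ribosomal protein, at -2.36 ± 1.41, SFT2D1 at -2.35 ± 1.51 and GATD1 at -2.30 ± 0.65, whose 2 other probes lay at -1.98 and -0.50. Of these 10 genes, DHX9 included, none passed limma's adjusted p, which was between 0.307 and 0.329. All 10 passed with an offset of 0 and with the processed signals, the latter with adjusted p between 0.00245 and 0.0114. Such calls depended on array 4. Refitted without array 4, 4 of all 972 genes called with the processed signals were still called, and 66 of the 688 with an offset of 0. How many of the 10 were among them is not given here.

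In all, 40 genes were at least 2-fold higher in Cy5 on every array, and 1 gene, C1QTNF5, was at least 2-fold higher in Cy3 on every array. Since Cy3 carried the same label on every array, a difference between dyes cannot be told apart from one between the libraries. Of the 40, 25 had a named symbol. Besides the 10 lowest these were GNL3L at -2.27 ± 0.59, a nucleolar GTPase, TM9SF3 at -2.29 ± 1.13, MAGOH at -2.26 ± 1.41, a core protein of the exon junction complex, SPA17 at -2.26 ± 1.38, FIP1L1 at -2.05 ± 0.80, a subunit of the polyadenylation factor CPSF, GNB4 at -1.97 ± 0.79, RSL24D1 at -1.97 ± 1.33, a factor of ribosome assembly, FAM20B at -1.96 ± 0.69, MAT2B at -1.94 ± 1.25, ZNF557 at -1.91 ± 1.05, USP47 at -1.85 ± 0.72, NICN1 at -1.79 ± 0.82, TLCD2 at -1.78 ± 0.39, IPP at -1.69 ± 0.78 and USP46 at -1.67 ± 0.78 (all SD, n = 4). For GNL3L, ZNF557, USP47 and FAM20B other probes came closer to 0, with values of up to -0.58, -0.56, -0.66 and -0.77. Those of FIP1L1, GNB4 and TM9SF3 reached -1.1, -1.19 and -1.36, and those of MAT2B, RSL24D1 and USP46 lay at -2, -1.99 and -1.63. All 40 had an adjusted p under 0.05 with an offset of 0, with the processed signals and with scaling between arrays. None had one in limma at the main setting. Calls with an offset of 0 and with the processed signals depended on array 4, as given below.

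**Figure D1:**
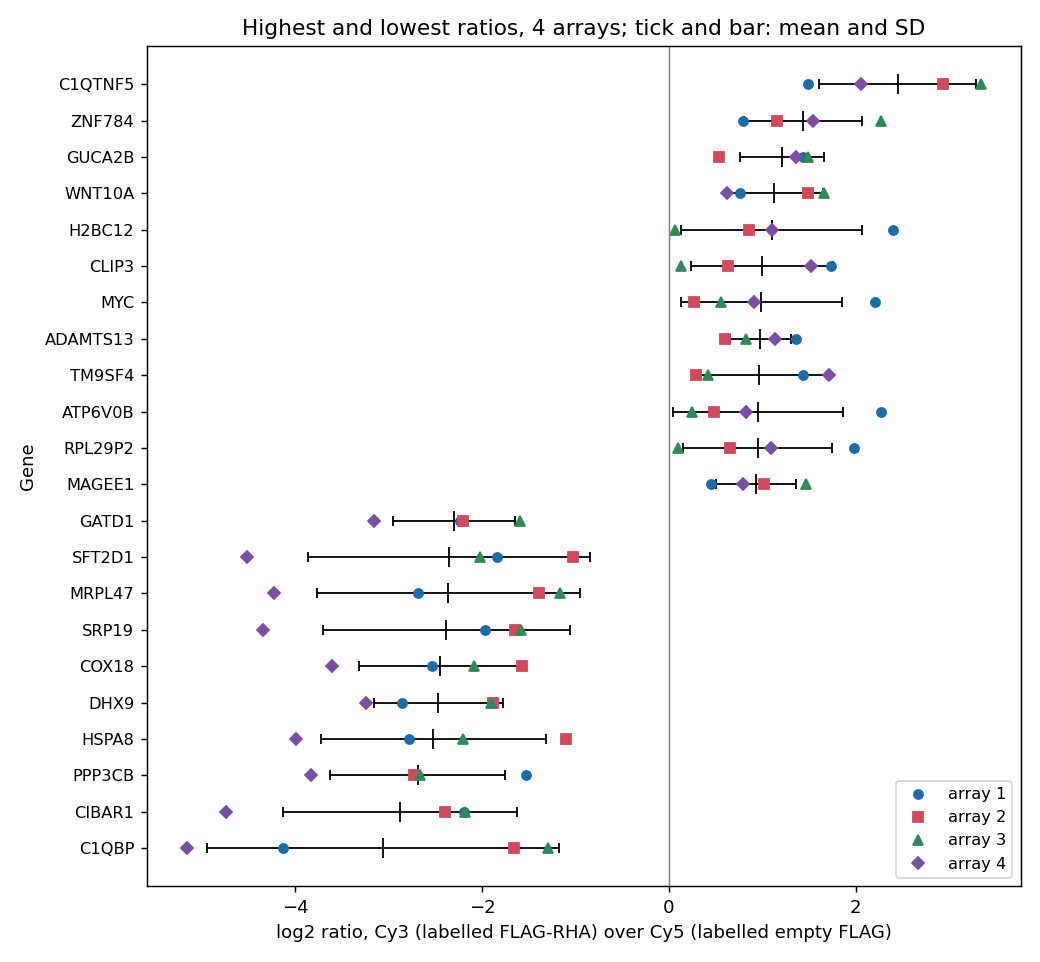
Log2 ratio of Cy3 (labelled FLAG-RHA) over Cy5 (labelled empty FLAG) for the 12 highest and 10 lowest named genes. Each symbol is 1 array, the black tick is the mean and the bar its SD over the 4 arrays. DHX9 lies at -2.47, and C1QTNF5, well above background in Cy5 on 2 of 4 arrays, is the highest at 2.45, a value that depends on the background treatment; with median or spike-in centring in place of loess, H2BC12, MYC, ADAMTS13, TM9SF4, ATP6V0B and RPL29P2 fall below 0, and CLIP3 does so with spike-in centring, while the median of all genes moves to -0.70 and -0.92.

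The highest ratios, toward the library labelled FLAG-RHA, were smaller. C1QTNF5, a secreted protein of the C1q and TNF family, had a ratio of 2.45 ± 0.84 (SD, n = 4), and was well above background in Cy5 on 2 of the 4 arrays. Its size depended on the background treatment, with a log2 ratio of 4.03 with an offset of 0 and 5.03 with the processed signals. ZNF784 followed at 1.44 ± 0.63, GUCA2B, the gut peptide uroguanylin, at 1.21 ± 0.45, WNT10A, a Wnt ligand, at 1.13 ± 0.52, and H2BC12, a histone H2B, at 1.10 ± 0.97. CLIP3 was at 1.00 ± 0.76, MYC at 0.99 ± 0.86, ADAMTS13, the protease that cleaves von Willebrand factor, at 0.98 ± 0.33, TM9SF4 at 0.97 ± 0.72, ATP6V0B, a subunit of the vacuolar proton pump, at 0.96 ± 0.91, RPL29P2 at 0.95 ± 0.80 and MAGEE1 at 0.93 ± 0.43. Several were not shared by a gene's other probes, which had means of 0.21 for MYC, of -0.02 and 0.01 for ADAMTS13, of 0.39 for CLIP3 and of 0.38 for TM9SF4. The adjusted p was 0.307 for C1QTNF5, ZNF784, GUCA2B, WNT10A and ADAMTS13 and between 0.321 and 0.395 for the rest. With the processed signals C1QTNF5, ZNF784, GUCA2B, WNT10A and MAGEE1 passed, at adjusted p of 0.00241, 0.014, 0.0111, 0.0151 and 0.0132. GUCA2B, WNT10A and MAGEE1 were then larger, at 1.99, 2.05 and 2.08, and with an offset of 0 at 1.93, 1.89 and 1.78. The size of these ratios thus also depended on the background treatment. C1QTNF5, GUCA2B, WNT10A and MAGEE1 were the dimmest of the highest genes listed, with mean log2 intensities of 7.2, 7.6, 7.4 and 7. The other highest genes listed lay between 8.6 and 13.3.

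Over all 19031 genes and unnamed transcripts, limma found 0 higher in Cy3 and 0 higher in Cy5 at an adjusted p of 0.05, and hence 0 at least 2-fold either way, the smallest adjusted p being 0.307. At an unadjusted p under 0.05 there were 689 higher in Cy3 and 1696 higher in Cy5, and a rank product over the arrays took 42 toward Cy3 and 399 toward Cy5. The ratio had the same sign on all 4 arrays for 4481 genes, or 23.5%, of which 3003 were higher in Cy5. If the arrays shared 1 control its error would recur on all of them, so no number expected by chance is given for these counts. The counts depended on the processing. With an offset of 0, limma called 51 genes higher in Cy3 and 637 higher in Cy5, and with the processed signals 65 and 907, of which 47 and 603 were the same genes. The processed signals also differ in dye normalisation, which the scanner's software had done and to which no loess was added. Without background subtraction limma called 0 and 0. The number of calls depended on array 4. Refitted without it, 4 of the 972 genes were still called with the processed signals and 66 of the 688 with an offset of 0, against 426 to 701 and 358 to 457 without any 1 other array. Without array 4 the median absolute log2 ratio of these genes was 1.49 against 1.68 and 1.19 against 1.46, and the median standard error 0.37 against 0.34 and 0.32 against 0.31.

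**Figure D2:**
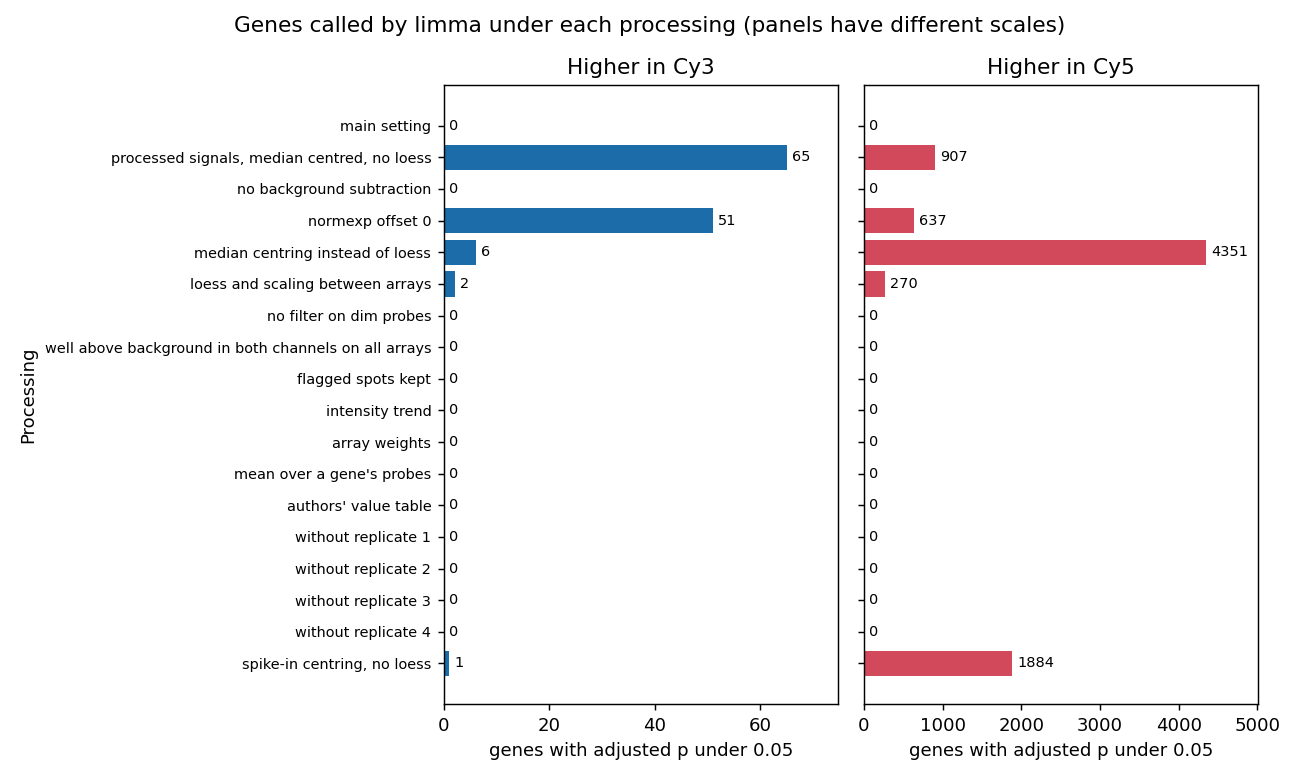
Number of genes with a limma adjusted p under 0.05 under each processing, higher in Cy3 on the left and higher in Cy5 on the right, as bars from 0 on linear axes of different range. The main setting and most alternatives gave 0 and 0; an offset of 0 gave 51 and 637, the processed signals 65 and 907, and median centring without loess 6 and 4351.

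The list of transcripts known to be handled by RHA had fewer than 3 members measured and was not tested, and JUND and COL1A1 are not analysed here. COL1A2, the type I collagen alpha 2 chain, was not well above background on any array in either channel. Among the 14 members of the AP-1 family measured, JUN was at -0.47 ± 0.60 (adjusted p = 0.445), MAFF at -0.51 ± 0.43 and JUNB at -0.32 ± 0.19, 5 members had means above 0 and 9 below, and camera's adjusted p was 0.623. The common reference genes GAPDH, at -0.40 ± 0.75, and ACTB, at -0.14 ± 0.56, had adjusted p of 0.549 and 0.802, and the mean over all ACTB probes was 0.11, above 0.

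The nuclear-encoded subunits of the respiratory chain were the 1 list of 20 tested that camera called. Of 74 measured, 51 had means above 0, toward Cy3, and 23 below, with a median log2 ratio of 0.24 and an adjusted p of 0.000777; the median turned to -1.07 with median centring and to -1.29 with spike-in centring, where that of all genes was at -0.70 and -0.92. Under these 2 centrings camera called the list in the opposite direction, toward Cy5, at adjusted p of 0.0171 and 1.2e-05. Centring shifts all ratios of an array alike, so it leaves in any dye difference that changes with intensity. Relative to all genes the list then lay at -0.37, the ribosomal proteins at -0.85 and the markers of other cell types at 0.54. The opposite direction was thus not particular to this list, and its cause was not tested. Fry gave the list an adjusted p of 0.932. The estimated correlation between its genes was 0.383, against the preset 0.01. With an estimated correlation the call was lost at the main setting (camera's adjusted p = 0.902) and under every alternative. At an offset of 50 camera with an estimated correlation also missed the simulated shifted list (adjusted p = 0.273). Losing a call in this way, here and below, therefore does not show that a list is unchanged. At the preset correlation the call was also lost with the processed signals (0.182) and the authors' value table (0.097), where the list median still lay 0.25 and 0.22 above that of all genes. The list medians on arrays 1 to 4 were 0.80, 0.24, -0.01 and 0.08. No single member passed, nor did any when adjusted over the list alone, and the members with the smallest p lay on the other side, NDUFS1 of complex I at -1.20 ± 0.82 and UQCRH of complex III at -1.39 ± 1.12 (SD, n = 4). A second probe of NDUFS1 lay at -0.70.

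Of the lists on translation, 46 of 79 ribosomal protein genes had means below 0, toward Cy5, and 20 did so on all 4 arrays against 1 with all 4 above 0. Camera's adjusted p was 0.379 and the list median -0.10. The list was called toward Cy5 without background subtraction (adjusted p = 0.0407), without replicate 1 (5.78e-05), with median centring (0.000483) and with spike-in centring (1.08e-19). All 4 calls were lost with an estimated correlation, at 0.884 or more. RPL5 was at -1.85 ± 0.96 and RPS2 at -1.48 ± 0.85 (SD, n = 4), with adjusted p of 0.307 and 0.321. The second probe of RPL5 lay at -1.24, and the other probes of RPS2 lay between -0.64 and -0.15. Among the other mRNAs with a 5' terminal oligopyrimidine tract 15 of 21 were below 0 (adjusted p = 0.655), led by PABPC1, the cytoplasmic poly(A)-binding protein, at -1.81 ± 1.08 and EIF3D at -1.25 ± 0.92. The RNA helicases were split, with 19 above and 18 below 0 (adjusted p = 0.776), and after DHX9 came DDX23 at -0.72 ± 0.66. The SR and hnRNP proteins had 17 above and 13 below 0 (adjusted p = 0.228), with HNRNPA0 at 0.86 ± 0.55, its second probe at 0.42, and SYNCRIP at -0.71 ± 0.58. That list was called toward Cy3 without replicate 2 (0.00359) and toward Cy5 with median centring (0.0107) and spike-in centring (0.0158), and each call was lost with an estimated correlation (0.844 or more). Of the microRNA machinery 10 lay above and 6 below 0 (adjusted p = 0.851). AGO3, an Argonaute protein, was at -0.89 ± 0.36 with an adjusted p of 0.307, or 0.0346 when adjusted over the list alone, and SND1 was at -0.81 ± 0.72.

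Among the long noncoding RNAs 8 of 12 had means above 0, with a median of 0.36. With median and spike-in centring it was -0.66 and -0.88, which is 0.04 above that of all genes. The list did not pass, at an adjusted p of 0.114, but was called toward Cy3 with the filter for both channels (0.022), with array weights (0.0117) and without replicate 1 (0.0191), each of which was lost with an estimated correlation (0.916 or more). The snoRNA host genes SNHG8 and SNHG1 were at 0.92 ± 0.80 and 0.70 ± 0.54 (SD, n = 4). The ZNF genes, a large family of zinc-finger transcription factors, were mostly below 0, with 254 of 383 there and a median of -0.12. Camera gave them an adjusted p of 0.114. With median and spike-in centring their median was -0.65 and -0.88, which lay 0.05 above that of all genes, the opposite side. They were called toward Cy5 with array weights (0.021), without replicate 1 (0.0377) and without replicate 3 (0.0209), and these calls too were lost with an estimated correlation (0.943 or more). ZNF784 at 1.44 and ZNF557 at -1.91 were the members with the highest and lowest ratios of those named, and ZNF426 was at -1.56 ± 0.65. The replication-dependent histones had 40 above and 20 below 0 (adjusted p = 0.330). They were called toward Cy3 without replicate 1 (0.00627) and without replicate 2 (1.75e-05) and toward Cy5 with array weights (0.01), median centring (0.00485) and spike-in centring (0.000636), and each call was lost with an estimated correlation (0.844 or more). Among them were H4C3 at -1.28 ± 0.53 and H4C13 at -1.08 ± 0.69; the histone H4 genes are near-identical copies that a probe may not tell apart.

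The growth control mRNAs, with MYC and with IGF2 at 0.55 ± 0.46 (SD, n = 4), had 12 of 24 on each side (adjusted p = 0.642). The heat shock proteins had 9 above and 10 below 0 (adjusted p = 0.902), and only HSPA8 passed when adjusted over the list alone, at 0.0177, while HSPB1 was at 0.64 ± 0.34. The unfolded protein response genes had 14 above and 11 below 0 (adjusted p = 0.776), with its transcription factor XBP1 at -2.06 ± 1.56 and PDIA6 at -0.79 ± 0.74. The proteasome subunits were split 17 and 17 (adjusted p = 0.852), with PSMD4 at -1.20 ± 0.97 and PSMA4 at -1.13 ± 0.90, and the interferon-stimulated genes 11 and 8 (adjusted p = 0.776), with EIF2AK2, the double-stranded RNA kinase PKR, at -1.07 ± 0.64 and IFIT5 at 0.45 ± 0.32. The second probe of PSMD4 lay at -0.63, and that of IFIT5 had the opposite sign, at -0.12. The cholesterol synthesis genes had 16 above and 8 below 0 (adjusted p = 0.345), with HMGCS1 at -0.50 ± 0.31, its second probe at -0.02, and FDFT1 at -0.87 ± 0.90. Mitotic genes had 16 above and 13 below 0 (adjusted p = 0.623), with CCNB2 at -1.21 ± 0.81 and TPX2 at -0.82 ± 0.51. The extracellular matrix genes were split 13 and 12 (adjusted p = 0.902), with COL4A2 at -0.73 ± 0.31 and COL6A1 at 0.46 ± 0.41, and the housekeeping mRNAs 9 and 16 (adjusted p = 0.778), with LDHA at -1.61 ± 1.47 (SD, n = 4). The second probe of COL6A1 lay at 0.04. Of 31 markers of other cell types 4 were measured (adjusted p = 0.623), among them CD79A at 0.47 ± 0.72 and ACTA1, well above background on 2 arrays in Cy3 and 3 in Cy5, at 0.11 ± 0.38. Transcripts of the mitochondrial genome were not analysed here. With an estimated correlation all 20 lists had an adjusted p of 0.902, and fry's smallest was 0.386, for the long noncoding RNAs. Camera's direction was toward Cy3 while the list mean lay below 0 for the helicases, proteasome, interferon, heat shock, unfolded protein, microRNA and mitosis lists.

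**Figure D3:**
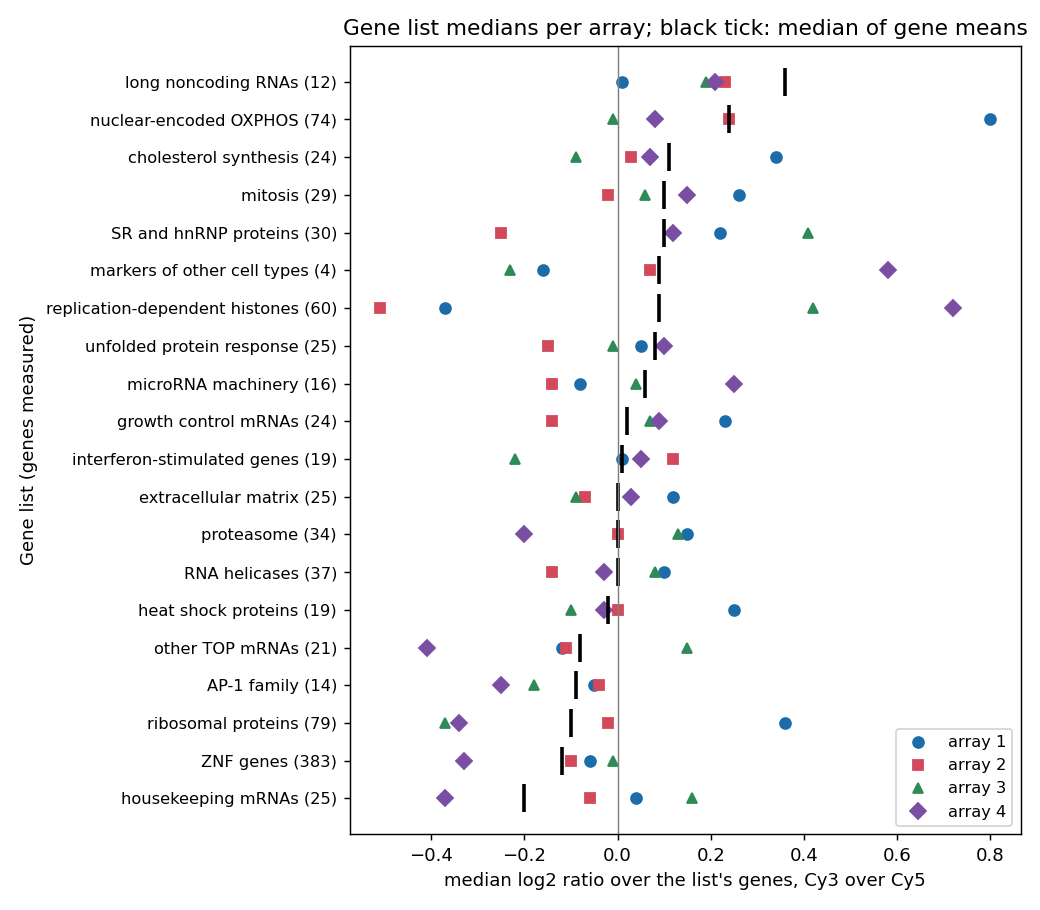
Median log2 ratio of Cy3 over Cy5 of each tested gene list on each array (symbols), with the median of the genes' means as a black tick and the number of genes measured in parentheses. The respiratory chain genes lie at 0.80 on array 1 and near 0 on arrays 3 and 4, and the histone genes at -0.37 and -0.51 on arrays 1 and 2 and at 0.42 and 0.72 on arrays 3 and 4; with median or spike-in centring in place of loess all medians of means fall below 0, as does that of all genes, at -0.70 and -0.92.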

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

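The tests of the direction of the ratios were chosen after the result was seen.

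Of 99 values and quality measures examined over the 4 arrays, 9 had 1 array far from the other 3. Chance would give about 5 if the 99 were independent. They are not, since most are genes on the same arrays, so 9 and 5 cannot be compared. For 8 of the 9 it was array 4, which also had the largest SD of log2 ratios over genes, at 0.818 against 0.307 to 0.705. It had the lowest log2 ratio of CIBAR1 (-4.74), MAGOH (-4.36), SRP19 (-4.34), RSL24D1 (-3.96), MAT2B (-3.80), ZNF557 (-3.48) and DDX23 (-1.71). Array 4 also stood apart in its Cy3 signal above local background, with a median of 108 intensity units against 9 to 14.5 on the others. GUCA2B was closer to 0 on array 2, at 0.54, than on the rest.

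The 10 spike-in controls, RNAs added at labelling and not used at the main setting, had a mean log2 ratio of Cy5 over Cy3 in the scanner's dye-normalised values of -0.21, -0.85, -3.66 and -1.41 on arrays 1 to 4. Relative to the spike-ins the sample RNA was thus brighter in Cy5 on each array, by 12.6-fold on array 3. This sets the mean over spike-ins of unlike design ratios to 0 and assumes like amounts in both channels.

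DHX9 and most of the large ratios were higher in Cy5: 40 genes were at least 2-fold that way on every array, and 1 gene the other way. The labels predict no direction for genes other than DHX9. For DHX9 they do so only if its mRNA was more abundant in the library labelled FLAG-RHA, which is an assumption. Turning the sign of some arrays gives 8 patterns, of which 1, the real one, gave as many genes (41 against at most 2 in the others), and 8 patterns are too few for a share under 0.05. Sequence-dependent dye bias of single probes is argued against for the 16 genes with further probes, since those had a median of -1.30 (95% bootstrap interval -1.999 to -1.169) and all 25 were below 0. The interval is over genes measured on the same 4 arrays, so it leaves out the spread between arrays. For the other 24 genes there was no second probe and such bias stays open. A dye effect shared by all probes of a gene stays open for all 40. An exchange of the dye labels on all arrays stays open. The 12 DHX9 values, 3 probes on 4 arrays, were all below -0.5, but they prompted this explanation and so do not test it, and the probes may miss the transfected part of DHX9. That the labels are right and these RNAs were recovered less with FLAG-RHA than with the empty plasmid also stays open and was not tested.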

How the results depend on the processing

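DHX9 stayed below 0 under all 17 alternatives, between -3.90 and -2.08, with adjusted p from 7.12e-07 to 0.674. The smallest came from spike-in centring, where limma's prior degrees of freedom were infinite, against 3.34 at the main setting. Each gene's own spread over the arrays then did not enter the test, so p-values of that setting are not comparable with the others. It passed the threshold, which it did not at the main setting, with the processed signals (-2.70), an offset of 0 (-2.55), median centring (-3.68), scaling between arrays (-2.41) and spike-in centring (-3.90). JUND is not analysed here. The added tests, chosen after seeing the data, are spike-in centring, the rank product and the counts of genes 2-fold toward 1 channel on every array. Calls higher in Cy3 and higher in Cy5 numbered 0 and 0 at the main setting, 65 and 907 with the processed signals (at least 2-fold, 65 and 907), 51 and 637 with an offset of 0 (51 and 636), 6 and 4351 with median centring (6 and 4217), 2 and 270 with scaling between arrays (1 and 228), 1 and 1884 with spike-in centring (1 and 1884) and 42 and 399 with the rank product, and 0 and 0 under the other alternatives, the test against a 2-fold change and each array left out included. The median of all genes moved to -0.11 with the processed signals, which the scanner's software had dye-normalised. It moved to -0.70 with median centring and -0.92 with spike-in centring, both without loess. Such a shift by itself adds genes toward Cy5. For the other changes the cause was not tested beyond the offset.

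Genes at least 2-fold toward Cy5 on every array numbered 40, against 324 with the processed signals, 61 without background subtraction, 119 with an offset of 0, 1214 with median centring, 73 with scaling between arrays, 742 with spike-in centring 69 in the authors' value table and 32 with the mean over a gene's probes, and between 40 and 115 without 1 replicate, where fewer arrays have to meet the bound. Toward Cy3 there was 1, against 17 with the processed signals, 7 with an offset of 0, 2 in the authors' value table, 0 with the filter for both channels, and between 1 and 6 without 1 replicate.

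Camera called 1 list, against 0 with the processed signals, 0 in the authors' value table, 0 with an estimated correlation, 2 without background subtraction, 2 with the filter for both channels, 4 with array weights, 10 with median centring, 11 with spike-in centring, and between 1 and 5 without 1 replicate. The 1 list called at the main setting, the respiratory chain, was called in the opposite direction, toward Cy5, with median and spike-in centring. Neither centring removes a dye difference that changes with intensity. Both centrings also called toward Cy5 the ribosomal proteins, other TOP mRNAs, RNA helicases, SR and hnRNP proteins, histones, proteasome, unfolded protein response, housekeeping and mitosis lists, and spike-in centring the heat shock proteins. The replication-dependent histones were called toward Cy3 without replicate 1 or 2 and toward Cy5 with array weights, and the SR and hnRNP proteins toward Cy3 without replicate 2. The ribosomal proteins were called toward Cy5 without background subtraction or replicate 1, the ZNF genes toward Cy5 with array weights and without replicate 1 or 3, and the long noncoding RNAs toward Cy3 with the filter for both channels, array weights and without replicate 1. With an estimated correlation 0 lists were called under every alternative, the smallest adjusted p being 0.844. At an offset of 50 that test also missed the simulated shifted list (adjusted p = 0.273), so it does not show that the lists are unchanged. The cause of the differences between settings was not tested.

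Of 1255 values of 74 other named genes under the alternatives, 1002 kept their direction and side of the threshold, 214 newly passed it and 39 changed sign, the cause of which was not tested beyond the shift of all genes. Median centring gave -0.10 for TM9SF4, -0.14 for H2BC12, -0.20 for IFIT5 and ADAMTS13, -0.22 for HNRNPA0, -0.29 for MYC, -0.33 for IGF2, -0.34 for ATP6V0B, -0.40 for RPL29P2, -0.45 for SNHG8, -0.65 for SNHG1, -0.68 for COL6A1 and -0.70 for HSPB1 and CD79A. Spike-in centring gave -0.068 for ACTA1, -0.11 for CLIP3, -0.33 for TM9SF4, -0.37 for H2BC12, -0.42 for IFIT5 and ADAMTS13, -0.45 for HNRNPA0, -0.51 for MYC, -0.55 for IGF2, -0.57 for ATP6V0B, -0.63 for RPL29P2, -0.67 for SNHG8, -0.88 for SNHG1, -0.91 for COL6A1, -0.92 for HSPB1 and -0.93 for CD79A. The processed signals gave -0.13 for IFIT5 and -0.16 for ACTA1, an offset of 0 gave -0.049 for ACTA1, array weights -0.071 for ACTA1 and the mean over probes 0.11 for ACTB. Leaving out 1 replicate gave ACTB between -0.35 and 0.05, ACTA1 between -0.068 and 0.21 and IFIT5 between -0.24 and 0.54. The dim Cy3 channel, with a median of 9 to 14.5 intensity units above background on arrays 1 to 3, limits all ratios of weak genes.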

Other observations

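The tests of the offset and of the sign patterns in this part were planned before their results were seen.

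With the scanner's processed signals, limma called single members in several lists. Of 79 ribosomal protein genes 4 were higher in Cy5 and 0 higher in Cy3, and of 383 ZNF genes 21 were higher in Cy5 and 2 in Cy3. Over all 19031 genes and unnamed transcripts 907 were higher in Cy5 and 65 in Cy3, which are similar shares. RPL21, chosen after its values were seen, had a log2 ratio of -2.14 ± 1.31 (SD, n = 4) at the main setting; many copies of this gene exist in the genome that a probe may not tell apart. XBP1, PABPC1, CCNB2, LDHA and H4C3 were also called, at adjusted p of 0.022, 0.0191, 0.0492, 0.0499 and 0.022. FOSB of the AP-1 family, COL3A1 of the extracellular matrix and ATP5PF of the respiratory chain list were called too, each higher in Cy5. Of all 972 genes called in this way, 4 were still called when refitted without array 4.

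The arrays agreed unevenly. Across 19017 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.52 between arrays 1 and 2, 0.44 between 2 and 4, 0.44 between 3 and 4, 0.38 between 1 and 4, 0.07 between 1 and 3 and -0.0011 between 2 and 3. The median of the 60 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, was -0.37 and -0.51 on arrays 1 and 2 and 0.42 and 0.72 on arrays 3 and 4.

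The number of calls changed from 0 to 688 when the background offset went from 50 to 0. Compression of dim arrays by the offset may contribute, since the largest array SD was 2.66 times the smallest with an offset of 50 and 1.98 times with 0, and the prior degrees of freedom went from 3.34 to 11, but 1.98 lies between the bounds set beforehand, so this cannot be told apart from other differences between arrays. That array 4 decides the number of calls is consistent with the test planned for it: without that array the processed signals gave 4 calls, against 481 or more without any 1 other array, and an offset of 0 gave 67. In the 972 genes called with the processed signals the median absolute log2 ratio was 1.49 without array 4 and 1.68 with it, and the median standard error 0.37 and 0.34. Without array 2 or 3 the error was larger, at 0.43 and 0.39, with a median ratio of 1.84 and 1.78, and 614 and 426 of the 972 were still called. Which of these changes ended the calls was not tested. No biological explanation was tested for this pattern.

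The 8 patterns of array signs are too few for a share under 0.05. The real signs, 1 pattern of the 8, gave 2386 genes with an unadjusted p under 0.05 among those measured on all arrays, against at most 1696 in the others, and 972 calls with the processed signals against at most 0.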
